A study of Mus musculus with 4 samples.

How the data were processed

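The series measured nuclear RNA of mouse dorsal root and nodose ganglia with a droplet-based 3′ kit (10x Genomics Chromium, v3.1 chemistry, per the labels' protocols). Per the submitters' processing notes, Cell Ranger 6.1.1 and the mm10 (GRCm38) genome were used. The counts deposited by the authors for the 2 dorsal root ganglion libraries were whole numbers of UMIs per gene and barcode, in filtered matrices of 32285 genes. The other deposited files held barcodes or gene names and no measurements. For the nodose ganglion samples only barcode and gene files were at hand, so their matrices were not analysed here. Whether reads in introns were counted, the annotation release behind the matrices, the deleted exons of Jak1 and the kind of Nav1.8-Cre allele were not given in the sources used here. The labels call the pools mixed in sex. Gene positions came from GENCODE vM21 (GRCm38), which held 32158 of the gene IDs. Of symbols that occur more than once, 40 later copies were given their gene ID as name.

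Barcodes with at least 500 genes and at most 5% mitochondrial UMIs were kept. In the littermate library 1263 barcodes had fewer genes and 685 exceeded the mitochondrial limit, and in the del-Jak1 library 1406 and 414. This left 80.4% and 85.7% of the barcodes. The median mitochondrial share was 0.609% and 0.782%, and 24212 and 25916 genes were detected. Scrublet (in scanpy 1.11.5), run per library, called 0 doublets in each, so doublets were in effect left in. As an alternative added after seeing the data, the 639 littermate and 1104 del-Jak1 nuclei with the highest Scrublet scores were removed, at an assumed rate of 0.8% per 1000 barcodes.

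Both libraries were clustered together without integration in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). The steps were log-normalisation, 2000 variable genes, 30 principal components, a shared-neighbour graph of 15 neighbours (scikit-learn 1.9.0) and Leiden clustering at resolution 1 with seed 1 (leidenalg 0.10.2, igraph 0.11.9), which gave 33 clusters. A cluster took the name of the type for which at least 3 fixed markers were over 2-fold higher than in the other nuclei, with 20 CPM added to both sides. It stayed without a name where neuronal and other markers were raised at once, or where its 10 top genes held more markers of another class. Scn10a-high neurons were the neuronal clusters with a mean Scn10a level, both libraries weighted equally, of at least 25% of that of the highest cluster. These were 7 clusters, and the other 4 neuronal clusters formed the Scn10a-low class. Classes with at least 100 nuclei in each library were compared, which gave 8 classes. A class is not compared in size where a marker that names it differed over 2-fold, and levels of the genes that lead the NP3 cluster are given for NP3 neurons from a clustering without the NP3 markers and named genes.

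UMIs were summed over the nuclei of a class in each library and divided by the class total to give CPM. Ratios are del-Jak1 over littermate on the log2 scale. CPM have exact Poisson intervals, ratios exact conditional binomial intervals, shares exact Clopper-Pearson intervals and differences of shares Newcombe intervals (statsmodels 0.14.6), all at 95%. A ratio with a count of 0 on a side would be given against a floor of 3 counts. With 1 pooled library per genotype there was no test, p-value or count of changed genes. List medians used members with at least 20 UMIs over both libraries, intervals from 200 Poisson resamples of the counts, and the percentile among 10000 random lists drawn from the 100 genes nearest in level to each member, which describes these 2 libraries only.

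The genes named were fixed by rule before the data were examined. The rule took Jak1 and Scn10a in every class, and the 12 highest and 12 lowest genes of Scn10a-high neurons by the bound of the interval nearest 0, among genes with at least 100 UMIs and at least 20 CPM in the higher library. It took 6 and 6 genes in Scn10a-low neurons, satellite glia and Schwann cells, and 3 and 3 in the smaller classes. Mitochondrially encoded genes, Xist, Y-linked genes, unnamed gene models and genes over 10 times higher in another class were left out. In Scn10a-high neurons 6033 genes qualified and 165 were left out as possible free RNA. It also took Calca, Calcb, Stat3, Il4ra, Il31ra, Osmr and Il6st, and 2 to 4 members with the largest and smallest ratios of each list. Values of Cysltr2 beside Il31ra were chosen after the ratios were seen, and some results under the rule for named genes are not reported here. The 20 lists, also fixed beforehand, covered JAK-STAT genes, cytokine receptors, interferon response, STAT3 targets, neuropeptides, excitability channels, pruriceptor receptors, axon injury, immediate early, heat shock, mitochondrially encoded, ribosomal protein, nuclear oxidative phosphorylation, cholesterol synthesis, myelin, glial activation, inflammatory and MHC class II, neurotrophin, synapse and sex-linked genes.

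Alternatives planned beforehand came to 15 settings and those added later to 4. The planned ones were at least 1000 or at least 200 genes, no mitochondrial limit, doublets kept, Leiden resolution 0.5 or 2, naming each nucleus by its highest marker score, thinning to 1000 UMIs per nucleus, TMM scaling (edgeR 4.0.16 in R 4.3.3), a total without mitochondrial, ribosomal and the 20 most abundant genes, equal weights of neuronal clusters, the mean of per-nucleus CPM, list members with at least 100 UMIs, Scn10a-high clusters at 50% of the highest, and naming genes from 50 UMIs with no CPM minimum. The added ones were removal of the highest doublet scores, subtraction of free RNA, clustering without the NP3 markers and named genes, and leaving out clusters of which 1 library held over 75%. Free RNA took the profile of the 2 mixed clusters of each library, at the largest share that every marker of the other lineage with at least 100 UMIs allowed. Its first form had assigned all UMIs of Scn10a-high neurons to free RNA and was replaced after this was seen. Details of the naming rule, the thinning depth and the lowest marker score of 0.5 were also set after seeing the data, the bounds of the test of interferon signalling were tightened after its result was seen, and the test of nuclear depth by thinning was replaced by one in nuclei matched on UMIs after the thinned values were seen. Equal numbers of nuclei of both libraries were drawn within bins of UMIs. The test of cytoplasmic or free RNA replaced one that had restated the pattern, and those of the number and depth of NP3 nuclei replaced ones that rested on markers with few UMIs and on a ratio that thinning does not move.

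The steps from class sums to ratios, named genes and list percentiles were run on simulated data. The counts were drawn from a Poisson distribution, the model behind the intervals, with no spread between nuclei or pools. The run thus checks the calculation, and not whether the intervals cover the spread of real libraries. In data with the depth of Scn10a-high neurons (11432 genes, of which 200 were changed), the intervals held the true ratio for 95.6% of unchanged and 97.5% of changed genes, and 24 of 24 named genes were changed ones. A list with no shift came out at percentile 38.5 and a list shifted by 0.5 on the log2 scale at percentile 100. At the depth of macrophages (861 genes) the shares were 95.5% and 97.5%, 6 of 6 named genes were changed ones, and the percentiles were 19.0 and 100. Figures were drawn with matplotlib 3.10.9.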

Results

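Nuclei of mouse sensory ganglia were profiled by droplet-based 3′ RNA sequencing in a model of asthma-like airway inflammation. C57BL6 mice aged 8 to 10 weeks received 2 µg of extract of the mould Alternaria into the nose each day for 4 days, and ganglia of 7 to 8 mice were pooled per sample on day 5. All mice were homozygous for a floxed allele of Jak1, the gene of a kinase that carries the signal of many cytokine receptors. The pool that also carried Nav1.8-Cre, a recombinase under control of the nociceptor sodium channel gene Scn10a, was called the del-Jak1 library after its label, and the other pool held Cre-negative littermates. There were 4 samples, 1 of thoracic dorsal root ganglia and 1 of nodose ganglia from each genotype, with no replicates. In the files used here, counts were at hand for the 2 libraries of dorsal root ganglia only. The littermate library held 9963 barcodes and 32233998 UMIs (unique molecules), and the del-Jak1 library held 12691 barcodes and 45882207 UMIs. After filtering, 8015 and 10871 nuclei were kept, with medians of 1680 and 1824 UMIs and of 1015 and 1090 genes per nucleus. The nodose ganglion samples came as barcode lists of 31058 (littermate) and 32428 (del-Jak1) barcodes and entered no comparison. With 1 library per genotype there was no measure of the spread between pools, so no test between genotypes was made. Each value is given with a 95% interval that covers counting error only: exact Poisson for CPM, the UMIs of a gene scaled by all UMIs of the class, exact conditional binomial for log2 ratios, Poisson resampling for list medians, and exact Clopper-Pearson for shares.

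The main comparison addressed transcripts of the neurons in which the Nav1.8-Cre driver is active. In these Scn10a-high neurons, receptor genes of itch neurons were among the lowest in the del-Jak1 library: Il31ra, a subunit of the receptor for the itch cytokine interleukin 31, was 13.6-fold lower, and the serotonin receptor gene Htr1f was 4.32-fold lower. Stat3, a transcription factor that acts downstream of JAK1, was also lower, as were 22 of 26 measured genes of the interferon response. The median log2 ratio of that list was -0.59, but -0.04 over the 12 members left in thinned nuclei, which had -0.28 unthinned. Neither Stat3 nor this list was lower in these neurons alone: Stat3 was also lower in fibroblasts, and 16 of 22 interferon response genes were lower in endothelial nuclei. In contrast, 18 of 22 neuropeptide genes were higher, as were 19 of 20 in satellite glia and 18 of 18 in fibroblasts, where the driver is not expected to be active. The Jak1 transcript itself was at nearly the same level in both libraries over the class as a whole. By subtype it went both ways, lower in NP3 itch neurons and higher in PEP1 and PEP2 neurons, as given below.

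Jak1 (ENSMUSG00000028530, GRCm38 chromosome 4, 101152367 to 101265282, minus strand) stood at 191 (183 to 199) CPM in littermate and 188 (181 to 195) CPM in del-Jak1 Scn10a-high neurons, a log2 ratio of -0.02 (-0.10 to 0.06). The class held 1376 littermate and 1398 del-Jak1 nuclei with 11580280 and 14802801 UMIs. The highest level was in NP3 neurons, a type of itch neuron known for somatostatin (Sst). There Jak1 was 1657 CPM in the littermate and 1439 CPM in the del-Jak1 library (log2 ratio -0.20, -0.33 to -0.08). Sst itself had only 17 and 25 UMIs in this cluster, whose name rests on other markers. In PEP2 neurons, which are A-delta nociceptors, Jak1 was 74.5 and 152 CPM, and in PEP1 neurons, which express substance P, it was 131 and 205 CPM. The 112 littermate and 86 del-Jak1 NP3 nuclei held 1195 and 851 UMIs of Jak1, so the class ratio depends strongly on them. Jak1 was found in 41.6% of littermate and 52.3% of del-Jak1 nuclei of the whole class. With 1000 UMIs drawn per nucleus these shares were 13.6% and 16.1%. The deleted exons were not given in the sources used here, and a 3′ tag that lies outside the deleted part does not show whether the gene was disrupted. The log2 ratio was -0.23 where Scn10a-high neurons were limited to clusters with at least 50% of the highest Scn10a level, -0.13 in nuclei with at least 1000 genes, and 0.07 with no mitochondrial limit.

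Scn10a (ENSMUSG00000034533, chromosome 9, 119608456 to 119719322, minus strand) was higher in the del-Jak1 library, with 1671 (1648 to 1695) CPM in littermate and 2408 (2383 to 2433) CPM in del-Jak1 Scn10a-high neurons. Its log2 ratio was 0.53 (0.50 to 0.55), and it was higher in 7 of the 7 clusters of the class. The class was drawn from the mean Scn10a level of both libraries, so its borders rest on this gene. Scn10a was also higher in Scn10a-low neurons (log2 ratio 0.77, 0.66 to 0.89) and in satellite glia (0.60, 0.46 to 0.75), which are not known to make it. The value in Scn10a-low neurons was 0.06 with the mean of per-nucleus CPM and 1.73 in nuclei with at least 1000 genes. With free RNA subtracted, the value was -0.54 in satellite glia and -0.17 in perineurial and meningeal nuclei, but 0.34 in fibroblasts and 0.14 in Schwann cells. The endothelial value was 1.13 and the macrophage value 0.62, and the lowest over all settings were 0.73 and 0.15. The kind of Nav1.8-Cre allele, knock-in or transgene, was not given, and these values do not tell a change of the intact gene from transcripts of an altered locus.

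The genes lowest in the del-Jak1 library included receptors and signalling genes of NP3 itch neurons. Il31ra (ENSMUSG00000050377, chromosome 13, 112519898 to 112594360, minus strand) stood at 202 (194 to 211) CPM in littermate and 14.9 (13.0 to 17.0) CPM in del-Jak1 Scn10a-high neurons, a log2 ratio of -3.77 (-3.97 to -3.57). Htr1f (ENSMUSG00000050783, chromosome 16, 64924729 to 65105854, minus strand) was 523 and 121 CPM, a log2 ratio of -2.11. Pde4c (ENSMUSG00000031842, chromosome 8, 70723720 to 70751186, plus strand), which encodes a cyclic AMP phosphodiesterase, was 168 and 30.8 CPM, a log2 ratio of -2.45. Gpr139, a G protein-coupled receptor gene, had a log2 ratio of -2.03. Osmr, whose product pairs with IL31RA in the interleukin 31 receptor, was 58.7 and 27.2 CPM. Stat3 (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540, minus strand) was 233 and 172 CPM, a log2 ratio of -0.44 (-0.52 to -0.36), and it was lower in 7 of the 7 clusters. It was also lower in fibroblasts (-0.40, -0.65 to -0.15) and in perineurial and meningeal nuclei (-0.56, -0.87 to -0.25).

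Several of these genes mark NP3 neurons, so the nuclei were also clustered without the NP3 markers and without the named genes. The NP3 cluster found in this way held 47 littermate and 46 del-Jak1 nuclei. These were deeper than the nuclei of the first NP3 cluster, which had medians of 3402.5 and 4298 UMIs. The new cluster was formed without the markers but named by them, and they include Il31ra, Htr1f, Osmr and Cysltr2. In the new cluster Il31ra was 3370 CPM in the littermate and 194 CPM in the del-Jak1 library, a log2 ratio of -4.12. Pde4c had a log2 ratio of -2.13 there, Htr1f of -1.83, Osmr of -0.89 and Gpr139 of -3.67. The leukotriene receptor gene Cysltr2, another marker of these neurons, was 1162 and 1029.7 CPM. The neuropeptide markers had few UMIs and went both ways, with 8 and 22 for Sst, 22 and 35 for Nts, and 4 and 3 for Nppb. In this cluster Il31ra had at least 1 UMI in 97.9% (88.7 to 99.9) of littermate and 63.0% (47.5 to 76.8) of del-Jak1 nuclei, at median depths of 9251 and 9270 UMIs. With 1000 UMIs drawn per nucleus, which left out 1400 littermate and 1827 del-Jak1 nuclei of all classes, these shares were 95.7% and 23.9%. Osmr was found in 95.7% of littermate and 91.3% of del-Jak1 nuclei of this cluster, and its log2 ratio was -0.69 (-1.57 to 0.15) when thinned. Satellite glia, which should lack Il31ra, showed 5.79% and 4.33% at median depths of 1947 and 2686 UMIs, and 3.07% and 1.06% when thinned. The del-Jak1 NP3 nuclei thus stayed above this free-RNA background.

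Other genes among the lowest differed outside NP3 neurons. Rasa4, which encodes a Ras GTPase activator, was 92.0 and 11.2 CPM in NP1 neurons, the Mrgprd-expressing nociceptors, and had a log2 ratio of -2.61 in Scn10a-high neurons. Nkain1 had a log2 ratio of -1.94, and Serping1, the gene of the complement C1 inhibitor, of -1.65. Serping1 was 136 and 37.8 CPM in NP1 neurons. Bcl6, a transcriptional repressor, had a log2 ratio of -1.39 in the class and -1.81 in NP1 neurons. The remaining genes of the 12 lowest were Mill2 (-1.42), a relative of the MHC class I genes, P4ha2 (-1.36), a collagen prolyl hydroxylase gene, Togaram2 (-1.37, and -0.43 in thinned nuclei) and Hsph1 (-1.19), a heat shock protein gene.

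**Figure D1:**
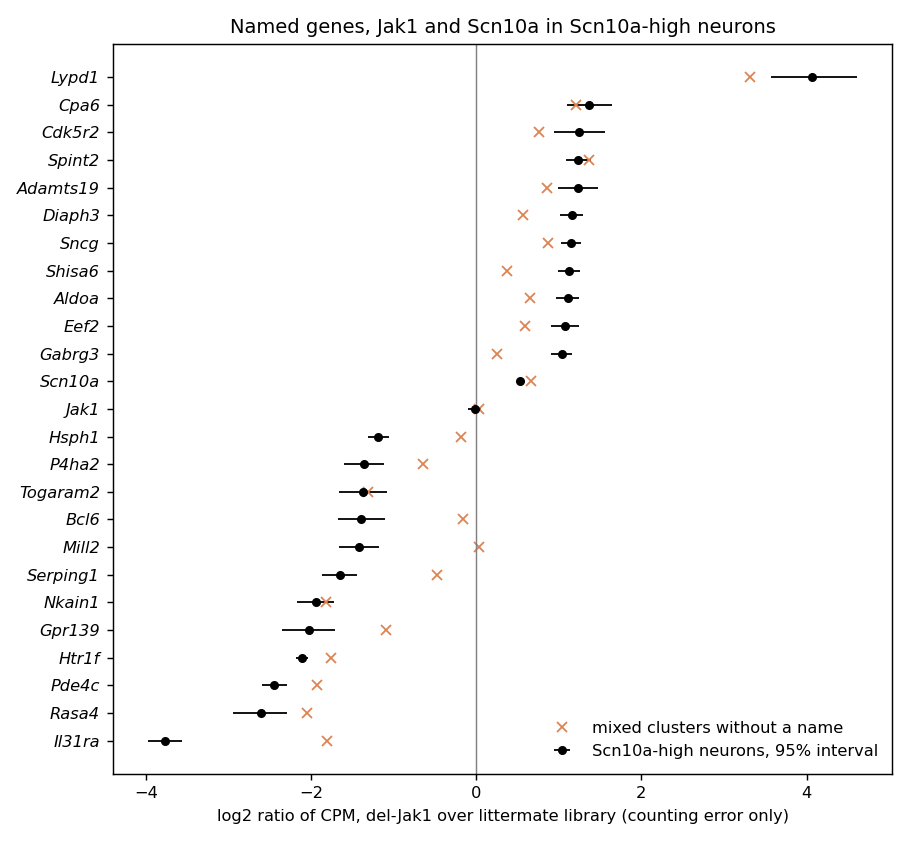
Log2 ratio of CPM, del-Jak1 over littermate library, for named genes, Jak1 and Scn10a in Scn10a-high neurons, with points for the ratio, bars for the 95% interval of counting error and crosses for the 2 mixed clusters without a name. Il31ra lies at -3.77, Jak1 at -0.02, Scn10a at 0.53 and Lypd1 at 4.07.

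Lypd1 (ENSMUSG00000026344, chromosome 1, 125867622 to 125913101, minus strand), whose product modulates nicotinic acetylcholine receptors, was among the genes highest in the del-Jak1 library. It was 2.94 and 49.3 CPM in Scn10a-high neurons, a log2 ratio of 4.07, and 6.02 and 133 CPM in NP1 neurons. Lypd1 was also higher in satellite glia (log2 ratio 3.39), in Schwann cells (3.21) and in the mixed clusters without a name (3.31). Other genes among the highest were Cpa6 (1.36), a carboxypeptidase gene, Spint2 (1.23, and 0.66 in clusters with at least 50% of the highest Scn10a level), Sncg (1.15), the gene of gamma-synuclein, Diaph3 (1.15), Adamts19 (1.23), Shisa6 (1.12), an auxiliary subunit gene of AMPA receptors, the glycolytic enzyme gene Aldoa (1.11), Cdk5r2 (1.25, and 0.65 in thinned nuclei), the translation elongation factor gene Eef2 (1.08) and the GABA receptor subunit gene Gabrg3 (1.03). Adamts19 was highest relative to the littermate library in NP3 neurons, with a log2 ratio of 2.49, Diaph3 in PEP1 neurons, with 1.67, and Shisa6 in NP1 neurons, with 1.63.

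**Figure D2:**
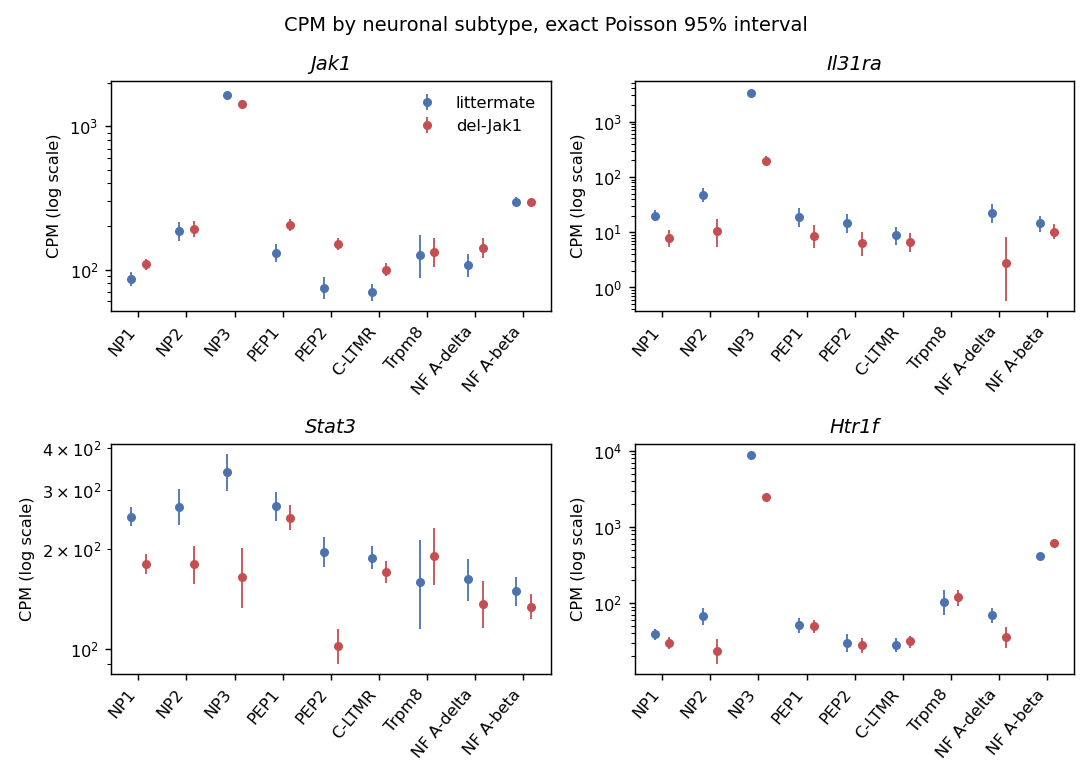
CPM of Jak1, Il31ra, Stat3 and Htr1f in 9 neuronal subtypes of the littermate and del-Jak1 libraries on a log scale, with points for the level and bars for the exact Poisson 95% interval. The NP3 points of Il31ra (3370 and 194 CPM) and Htr1f (8752 and 2470 CPM) come from the clustering without the NP3 markers and named genes, because both lead the NP3 cluster of the first clustering. No point is drawn for Il31ra in Trpm8 neurons, which held too few UMIs.

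The gene lists tied to JAK1 signalling were lower or mixed in the del-Jak1 library. Of 26 measured genes of the interferon response, 4 were higher and 22 lower, with a median log2 ratio of -0.59 (-0.79 to -0.41), at percentile 0 of 10000 random lists matched on level. Ifit1, an antiviral gene, was 7.25 and 1.35 CPM and Parp14 7.25 and 3.24 CPM, while the MHC class I genes B2m (log2 ratio 0.51) and H2-D1 (0.31) were higher. Most members had few UMIs: with at least 100 UMIs required the median was -0.31, and in thinned nuclei, where 12 members remained, it was -0.04 (-0.40 to 0.27), against -0.28 for the same members unthinned. The pooled log2 ratio of the members was -0.35 and, when thinned, -0.28. Of 23 JAK-STAT genes, 6 were higher and 17 lower, with a median of -0.11 (-0.18 to -0.04) at percentile 0.645. Stat2 had a log2 ratio of -0.66, the feedback inhibitor gene Socs4 of 0.41 and Pias3 of 0.44. Of 22 cytokine receptor genes, 8 were higher and 14 lower, with a median of -0.15 (-0.20 to 0.02) at percentile 0.25. Besides Il31ra, Il13ra1 had a log2 ratio of -1.14 and Il4ra, its partner for interleukins 4 and 13, of -0.39, whereas Il6st, the shared subunit gp130, had 0.53 and Lepr, the leptin receptor gene, 0.47. The Il4ra value was -1.16 in thinned nuclei and -0.015 in nuclei with at least 1000 genes. The cytokine receptor median was 0.07 in clusters with at least 50% of the highest Scn10a level.

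The list of STAT3 targets showed no common direction, with 9 of 15 members higher and 6 lower. Its median was 0.12 (-0.17 to 0.32) at percentile 34.2, and 0.43 in clusters with at least 50% of the highest Scn10a level. It turned to -0.10 with members of at least 100 UMIs and to -0.02 (-0.45 to 0.38) in thinned nuclei. Bcl6 and Bcl3 (log2 ratio -1.27) were its lowest members, and the neuropeptide gene Gal (1.22) and the kinase gene Pim1 (0.53) its highest.

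In Scn10a-high neurons, neuropeptides and their processing enzymes were higher in the del-Jak1 library, and itch receptors lower. Of 22 neuropeptide genes, 18 were higher and 4 lower, with a median log2 ratio of 0.40 (0.34 to 0.47) at percentile 100. The pooled log2 ratio of the members was 0.16 and, when thinned, 0.15. The list was also higher in classes that are not known to make most of these peptides, with medians of 0.51 in satellite glia (19 of 20 members higher), 0.44 in fibroblasts (18 of 18) and 0.36 in endothelial nuclei (17 of 17). The estimated free-RNA share was higher in the del-Jak1 library in each of them, and with free RNA subtracted these medians were 0.12, 0.26 and 0.16. The share in Scn10a-high neurons was 5.16% in the littermate and 6.40% in the del-Jak1 library. Calca, the gene of the peptide CGRP, was 160.2 and 219 CPM (log2 ratio 0.45), Calcb 40.6 and 55.9 CPM, and Nmb, which encodes neuromedin B, 25.1 and 46.4 CPM, while the secretogranin gene Scg3 had a log2 ratio of -0.49. Calca was higher in NP1 neurons (0.37) and lower in NP2 neurons (-0.87), the Mrgpra3-expressing itch neurons. The neuropeptide median was 0.63 with no mitochondrial limit and 0.64 where nuclei were named by their own marker scores. Ribosomal protein and nuclear oxidative phosphorylation genes had medians of 0.46 and 0.48 in the same neurons, also at percentile 100. Random lists were matched on level only, so percentile 100 does not set the neuropeptides apart from these lists. Of 17 pruriceptor receptor genes, 3 were higher and 14 lower, with a median of -0.55 (-0.67 to -0.40) at percentile 0. The median of this list was also below 0 in some classes where the driver is not expected to be active, with -0.68 (-1.05 to 0.02) in endothelial nuclei, -0.54 (-0.74 to -0.03) in perineurial and meningeal nuclei and -0.40 (-0.79 to -0.02) in Schwann cells. The first of these turned to 0.04 in thinned nuclei, and the last 2 to 0.25 and 0.01 in nuclei with at least 1000 genes. In fibroblasts the list had a median of 0.17. Il31ra and Htr1f were its lowest members in Scn10a-high neurons, and Mrgpra3 (1.13) and Mrgprx1 (0.42), the chloroquine and BAM8-22 receptor genes, its highest. Of 39 excitability channel genes, 24 were higher and 15 lower, with a median of 0.03 (0.01 to 0.10) at percentile 69.7, which turned to -0.03 with TMM scaling. The purinergic receptor gene P2rx3 (-0.57) and Cacna2d2 (-0.43) stood lowest in this list, and the potassium channel genes Kcna2 (0.63) and Kcnt2 (0.53) highest.

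Genes of ribosomal proteins and of oxidative phosphorylation were mostly higher, and mitochondrially encoded genes mostly lower. Of 91 genes matched by the ribosomal protein pattern, which also takes in some S6 kinase genes, 86 were higher in del-Jak1 Scn10a-high neurons, with a median of 0.46 (0.41 to 0.50) and with Rpl28 at 1.11. Of 87 nuclear genes of oxidative phosphorylation, 81 were higher, with a median of 0.48 (0.43 to 0.52) and with Ndufa13 at 1.10. Of 13 mitochondrially encoded genes, 10 were lower, with a median of -0.30 (-0.33 to -0.27) and with mt-Co1 at -0.78. Among 18 axon injury genes, 9 were higher and 9 lower, with Atf3 at -1.13, Bdnf at -0.97 and Gadd45a at 0.77. Among 18 immediate early genes, 10 were higher, with Dusp6 at 1.04 and Klf6 at 0.55. Among 17 heat shock genes, 10 were lower, with Chordc1 at -0.53 besides Hsph1, and Hspa8 (0.77) and Hspb1 (0.71) higher. Of 17 neurotrophin receptor and nociceptor factor genes, 12 were higher, with Ngfr, the p75 receptor gene, at 0.82 and Gfra3 at -0.60.

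**Figure D3:**
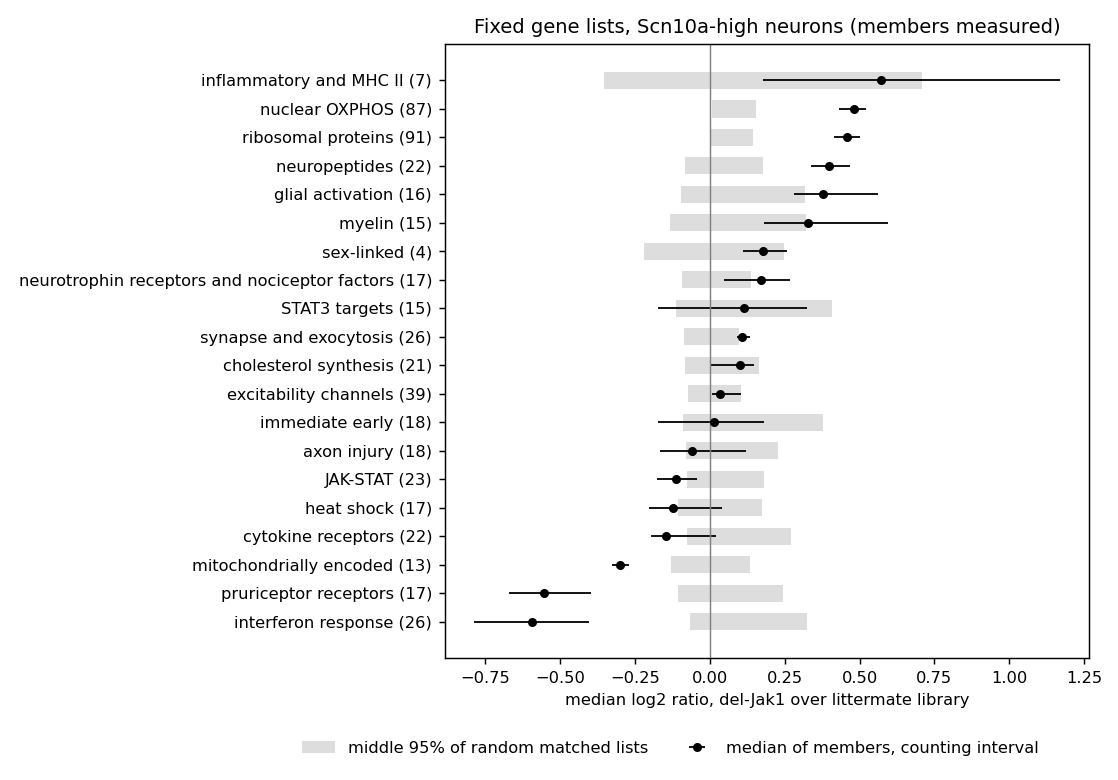
Median log2 ratio, del-Jak1 over littermate library, of 20 gene lists in Scn10a-high neurons, with the number of measured members in brackets, points and bars for the median and its counting interval, and grey bars for the middle 95% of random matched lists. The interferon response lies at -0.59, pruriceptor receptors at -0.55, neuropeptides at 0.40 and ribosomal proteins at 0.46.

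Neurons made up a smaller share of the del-Jak1 nuclei, and nuclei in clusters without a name a larger one. Shares of single types of the ganglion were compared only where none of their fixed markers differed over 2-fold between the libraries. Neurons as a whole also held types with such markers, namely NP2 (Mrgprb4, Mrgprb5), NP3 (Il31ra, Htr1f) and PEP1 neurons (Adra2a), all in the Scn10a-high class, and A-beta neurons (Pvalb, Spp1). Neurons made up 2031 littermate nuclei (25.3%, 24.4 to 26.3) and 1996 del-Jak1 nuclei (18.4%, 17.6 to 19.1), a difference of -6.98 percentage points (-8.18 to -5.78). Clusters without a name, most of which mixed neuronal and glial transcripts, held 28.2% (27.2 to 29.2) of littermate and 44.8% (43.8 to 45.7) of del-Jak1 nuclei. Among nuclei in named clusters, neurons were 35.3% and 33.2%, and this difference of -2.03 points turned to 3.83 points at Leiden resolution 2. Where nuclei were named by their own marker scores, the difference among all nuclei was -1.53 points.

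Within neurons, the Scn10a-high class made up 67.8% (1376 of 2031) in the littermate and 70.0% (1398 of 1996) in the del-Jak1 library. The difference of 2.29 points (-0.57 to 5.14) was not detectable at this depth, and it was -6.07 points where nuclei were named by marker scores. PEP2 nociceptors were 8.47% (7.29 to 9.77) and 11.5% (10.1 to 13.0) of neurons, a difference that fell to 0.376 points in nuclei with at least 1000 genes. C-LTMR neurons, the low-threshold C-fibre mechanoreceptors, were 18.2% (16.5 to 19.9) and 15.2% (13.7 to 16.9), a difference of -2.94 points that was -6.47 in nuclei with at least 1000 genes. NP1 neurons were 19.5% and 21.2%, a difference of 1.74 points that turned to -3.74 where nuclei were named by marker scores, and Trpm8 cold-sensing neurons 1.97% and 2.61%. A-delta low-threshold mechanoreceptors were 12.9% and 6.21%, a difference that turned to 0.0933 points in nuclei with at least 1000 genes. Nuclei that carried markers of spinal cord cells numbered 398 in the littermate (4.97%, 4.50 to 5.46) and 13 in the del-Jak1 library (0.120%, 0.0637 to 0.204), too few to compare their markers between the libraries. Myelinating Schwann nuclei were 5.74% (5.24 to 6.27) and 8.15% (7.64 to 8.68) of all nuclei, a difference of 2.41 points (1.68 to 3.13) that was 1.41 without the highest doublet scores and 5.31 with at least 1000 genes. They were 7.99% and 14.8% of nuclei in named clusters, a difference of 6.77 points. Endothelial nuclei were 3.24% (2.87 to 3.66) and 3.42% (3.09 to 3.78) of all nuclei, but 4.52% (3.99 to 5.08) and 6.20% (5.60 to 6.84) of those in named clusters. Mural nuclei were 0.786% and 0.644% of all nuclei, but 1.09% and 1.17% of those in named clusters.

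**Figure D4:**
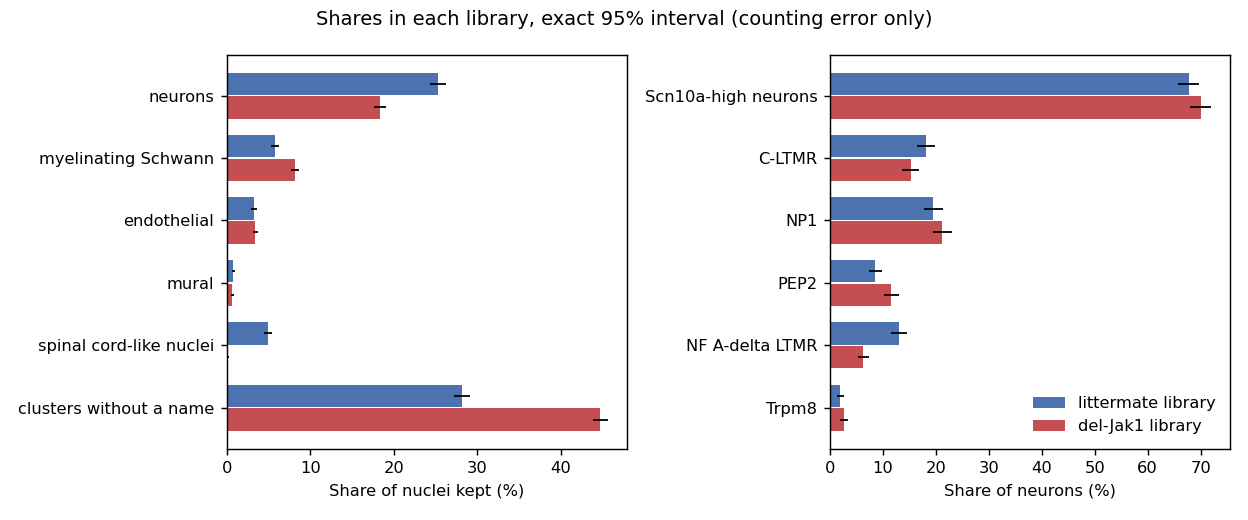
Shares of nuclei kept (left, %) and of neurons (right, %) in the littermate and del-Jak1 libraries, with bars for the share and lines for the exact 95% interval of counting error. Neurons were 25.3% and 18.4% of nuclei, clusters without a name 28.2% and 44.8%, and Scn10a-high neurons 67.8% and 70.0% of neurons.

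The same contrast was measured in the classes outside Scn10a-high neurons. Scn10a-low neurons still held Scn10a, at 581 CPM in A-delta mechanoreceptors and 404 CPM in Trpm8 neurons (mean of both libraries). Activity of the Nav1.8-Cre driver in some of them is thus not excluded. In Scn10a-low neurons, which are mostly mechanoreceptors and proprioceptors (655 littermate and 598 del-Jak1 nuclei), Aldh1a3, a retinoic acid synthesis gene, was 2.51 and 25.3 CPM, and the neuropeptide gene Nts 5.76 and 35.8 CPM. Sema5a (1.45), Pzp (1.83) and Ccdc30 (1.46) were also among the highest genes. The lowest were P2rx3 (-1.26), Sh2d4b (-1.20), Slc12a3 (-1.16), P4ha1 (-1.06), Ptprt (-0.98) and Lpar3 (-1.21), of which Lpar3 turned to 0.20 at Leiden resolution 2. In nuclei with at least 1000 genes P2rx3 was -0.09 and Ptprt -0.22, and Nts was 0.70 where nuclei were named by marker scores, against 2.64. P2rx3 and Sh2d4b were higher in 2 and lower in 2 of the 4 clusters of the class, in which A-delta mechanoreceptors made up 263 of 655 littermate and 124 of 598 del-Jak1 nuclei, and with equal weights of clusters they had log2 ratios of -0.85 and -0.71. Jak1 was 230.2 and 251 CPM. Of 21 cholesterol synthesis genes, 19 were lower, with a median of -0.23 (-0.32 to -0.12) that turned to 0.13 at Leiden resolution 2. The interferon response list had a median of -0.10 (-0.27 to 0.22) and the JAK-STAT list of -0.01.

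Lypd1 was the highest gene of both glial classes, and Il31ra was among the lowest of each. Lypd1 was 3.56 and 37.2 CPM in satellite glia, next to 9.86 and 97.8 CPM in the mixed clusters used as the free-RNA profile. With free RNA subtracted, its log2 ratio in satellite glia was 2.30 against 3.39. In satellite glia (1105 and 786 nuclei), Fstl4 was 24.1 and 133 CPM, the cystatin C gene Cst3 58.1 and 198 CPM, Dbi 112 and 329 CPM, and the intermediate filament gene Vim 105 and 306 CPM. Zbtb16 (log2 ratio -1.53), Zmat4 (-1.51), Il31ra (-1.61), Kcnip4 (-0.89), Asic2 (-0.93) and Pde10a (-0.79) were lowest. Where nuclei were named by marker scores, Zmat4 was -0.53, Kcnip4 -0.28 and Asic2 -0.52. With free RNA subtracted they were -2.97, -1.85 and -1.67. Kcnip4 was 1847 and 994 CPM in satellite glia, next to 3015 and 2267 CPM in the mixed clusters. In Schwann cells (750 and 1227 nuclei), the metallothionein genes Mt1 (1.76) and Mt2 (1.73), Ly86 (1.80), Fxyd7 (1.92) and Gapdh (1.44) were higher. Gpnmb (-2.10), Adamts12 (-1.76), Il31ra (-1.97), Adgrb3 (-1.29), Tspan18 (-1.40) and Fras1 (-1.63) were lower, and Fras1 turned to 0.07 where nuclei were named by marker scores. Gpnmb was higher in 2 and lower in 1 of the 3 Schwann clusters, and Adamts12 higher in 1 and lower in 2, while non-myelinating nuclei were 290 of 750 littermate and 341 of 1227 del-Jak1 Schwann nuclei. The free-RNA share estimated for satellite glia was 17.3% in the littermate and 30.2% in the del-Jak1 library, and for Schwann cells 21.3% and 24.5%. Jak1 was 148 and 160 CPM in satellite glia and 154 and 156 CPM in Schwann cells.

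The median of the JAK-STAT genes was below 0 in each class outside the neurons, with an interval below 0 in fibroblasts alone. It was -0.21 (-0.30 to -0.01) in fibroblasts at percentile 0.57, -0.26 (-0.45 to 0.03) in endothelial nuclei at percentile 0.625, and -0.20 (-0.32 to 0.06) in perineurial and meningeal nuclei at percentile 1.59. It was -0.14 (-0.23 to 0.01) in Schwann cells, -0.09 (-0.23 to 0.01) in satellite glia and -0.08 (-0.47 to 0.14) in macrophages at percentile 15.9. In thinned nuclei it turned to 0.10 in the perineurial and meningeal class and to 0.19 in macrophages. The perineurial and meningeal class mixed cluster 7, with 348 littermate and 232 del-Jak1 nuclei, and cluster 17, with 69 and 284. The interferon response list had a median of -0.16 (-0.34 to 0.05) in satellite glia and was lower in endothelial nuclei, with 16 of 22 members lower and a median of -0.40 (-0.74 to -0.13), and had a median of 0.40 (0.11 to 0.75) in perineurial and meningeal nuclei. Whether any of these medians differed from those of Scn10a-high neurons was not tested.

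**Figure D5:**
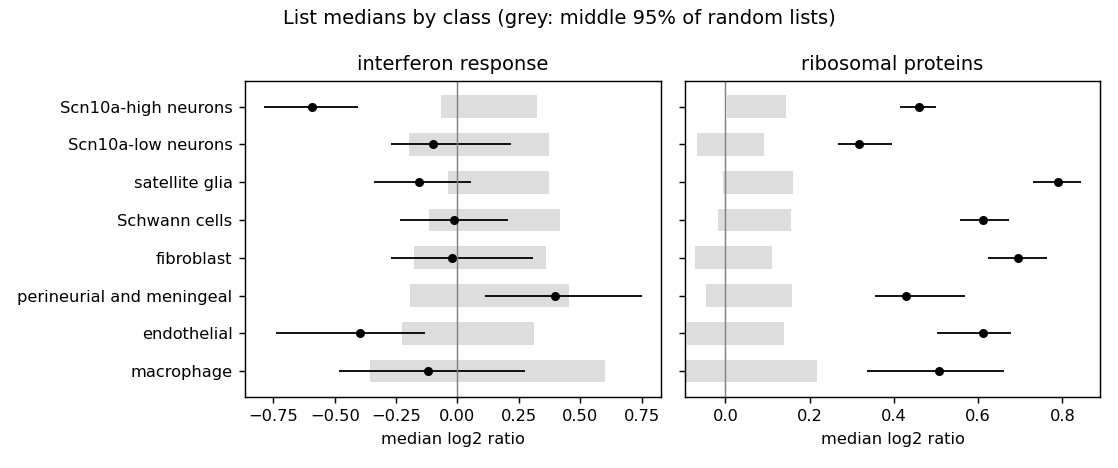
Median log2 ratio, del-Jak1 over littermate library, of the interferon response and ribosomal protein lists in 8 classes, with points and bars for the median and its counting interval and grey bars for the middle 95% of random matched lists. The interferon response median is -0.59 in Scn10a-high neurons, -0.40 in endothelial nuclei and 0.40 in perineurial and meningeal nuclei, and the ribosomal protein median is above 0 in all 8 classes.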

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

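Nuclei in clusters that no cell type name covered entered no comparison of gene levels, and they made up 44.8% (43.8 to 45.7) of the del-Jak1 library against 28.2% (27.2 to 29.2) of the littermate library. Most lay in cluster 0, with 1925 littermate and 3990 del-Jak1 nuclei at a median of 1197 UMIs, whose top genes included the neurofilament genes Nefh and Nefl while satellite glia markers were raised. Cluster 3 held 151 and 601 nuclei with neuronal and satellite glia markers at once, and cluster 10 held 181 and 276 nuclei led by Slc47a1, Slc4a10 and Col25a1. No biological explanation of the difference was tested. Where each nucleus was named by its own marker score, the share without a name was 4.46 percentage points lower in the del-Jak1 library.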

How the results depend on the processing

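Removal of the highest doublet scores, subtraction of free RNA, clustering without the NP3 markers and named genes, and leaving out clusters held by 1 library were chosen after seeing the data. No paired analysis was possible because each genotype had 1 pooled library, and no result has a test whose threshold an alternative would cross. A value counts as moved where it left its interval of counting error. The counts of changed sign below do not hold every turn of sign. Results whose own interval held 0 turned as well, such as Jak1 from -0.02 to 0.07 and the cytokine receptor median from -0.15 to 0.07. The share of Scn10a-high neurons among neurons turned from 2.29 to -6.07 points. Of 166 alternative values for the 10 results that answer a comparison, 131 stayed inside that interval, 34 moved and 1 changed sign. Of 2787 for the other 183 results, 2337 stayed inside, 427 moved and 23 changed sign. Among these were 408 for the 24 named genes of Scn10a-high neurons, of which 343 stayed inside, 65 moved and 0 changed sign. Which genes are named depends on the cut: with at least 50 UMIs and no CPM minimum, 9 of the 24 were named again. Keeping doublets changed nothing because none were called, and leaving out clusters held by 1 library gave no value for spinal cord-like nuclei, since none remained. The values below follow the order of settings, and the cause was not tested. Units are log2 for genes and medians and percentage points for shares, and values are for Scn10a-high neurons unless another class is named.

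With at least 1000 genes, Jak1 was -0.13, Scn10a 0.56, neuropeptides 0.50, the share of Scn10a-high neurons among neurons -4.90, Lpar3 in Scn10a-low neurons 0.036, Atp13a5 in perineurial and meningeal nuclei -1.35, the median of pruriceptor receptors in Schwann cells 0.00758 and in perineurial and meningeal nuclei 0.25, and the A-delta mechanoreceptor share 0.0933. With at least 200 genes, neuropeptides were 0.49 and in Schwann cells -0.013, the share of neurons, all nuclei kept, was -5.14 and the share of neurons, nuclei in named clusters, 0.0627. With no mitochondrial limit, Jak1 was 0.067, neuropeptides 0.63, excitability channels 0.15 and neurons -5.11. At Leiden resolution 2, neuropeptides were 0.53, the Scn10a-high share -4.71, neurons -2.35 of all nuclei and 3.83 of named ones, Atp13a5 in perineurial and meningeal nuclei -0.21, Lpar3 in Scn10a-low neurons 0.20 and cholesterol synthesis there 0.13.

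Where nuclei were named by marker scores, Scn10a was 0.49, interferon response -0.25, neuropeptides 0.64, the Scn10a-high share -6.07, neurons -1.53, A-delta mechanoreceptors 0.356, satellite glia 0.962 against -6.56 (-7.46 to -5.66), a share not compared because their markers Apoe and Fabp5 differed over 2-fold, nuclei without a name -4.46, Fras1 in Schwann cells 0.069 and pruriceptor receptors there 0.059. In thinned nuclei Scn10a was 0.73, JAK-STAT -0.21, interferon response -0.038, neurons -8.18 and the median of neuropeptides in Schwann cells -0.00652. With Scn10a-high neurons at 50% of the highest cluster, Jak1 was -0.23, Scn10a 0.56, STAT3 targets 0.43, cytokine receptors 0.065 and excitability channels 0.11. With TMM scaling, Scn10a was 0.47, cytokine receptors -0.21, excitability channels -0.026 and neuropeptides 0.34. With equal weights of clusters, Scn10a was 0.60 and neuropeptides 0.32. With the mean of per-nucleus CPM, Scn10a was 0.70. With members of at least 100 UMIs, interferon response was -0.31. With free RNA subtracted, Scn10a was -0.54 in satellite glia and -0.17 in perineurial and meningeal nuclei, and neuropeptides in Schwann cells -0.11. Clustered without the NP3 markers and named genes, Atp13a5 in perineurial and meningeal nuclei was -0.23 and neurons of named nuclei 1.08. Without clusters held by 1 library, Atp13a5 was -0.20. Atp13a5 leads cluster 17 of that class and is not given as a result.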

Other observations

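All tests below were chosen after the results were seen, except that of the interferon response, whose bounds were tightened after its result was seen. In the smaller classes, fibroblasts of the del-Jak1 library held more of the metallothionein gene Mt1 (24.4 and 103 CPM) and of Prg4, the lubricin gene (21.6 and 88.9 CPM), and Aldoa had a log2 ratio of 1.58. The growth-response gene Egr1 was lower (68.4 and 16.9 CPM), as were the Wnt antagonist gene Dkk2 (-1.94) and Pde10a (-1.46), and 10 of 14 immediate early genes were lower with a median of -0.36 (-0.70 to -0.15). In perineurial and meningeal nuclei, of clusters 7, 17 and 27, the phosphodiesterase gene Pde7b was 696 and 154 CPM, Pax9 106 and 18.3 CPM, and Zbtb16 522 and 141 CPM. In endothelial nuclei Apoe (1.45), Zfp804a (1.69) and the interleukin 1 receptor gene Il1r1 (1.77) were higher, and Htr1f (-1.60), Pde7b (-1.24) and Zbtb16 (-1.39) lower. Htr1f was 174 and 57.2 CPM there, next to 174 and 51.4 CPM in the mixed clusters used as the free-RNA profile, and the estimated free-RNA shares were 22.4% and 33.9%. In macrophages Rbpj, the Notch effector gene, was 699.6 and 1607 CPM, and the glucocorticoid-induced gene Fkbp5 was 443 and 160.1 CPM, with Lrp1b (-1.46) and Ccnd3 (-0.97) also lower. The neuronal genes Nefl and Map1b had log2 ratios of 1.39 and 1.11 in macrophages, where the estimated free-RNA share was 0% in the littermate and 7.42% in the del-Jak1 library, and Nefl was 1310 and 2034 CPM in the mixed clusters. The share is the largest that every marker allows, so 1 marker can set it to 0. Macrophages held 444 CPM of the neuronal gene Scn10a (mean of both libraries), so the 0% does not show that free RNA was absent. The MHC class II and inflammatory list had 4 measured members in macrophages, and 4 of them were higher, with a median of 1.23 (0.79 to 1.85), or 0.63 where nuclei were named by marker scores, and Cd74 at 146 and 246 CPM.

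The remaining lists in Scn10a-high neurons had medians of 0.10 for cholesterol synthesis (12 of 21 members higher), 0.11 for synapse and exocytosis (18 of 26), 0.33 for myelin (14 of 15), 0.38 for glial activation (13 of 16) and 0.57 for inflammatory and MHC class II genes (6 of 7). Complement C4b (1.77) and the alarmin gene Il33 (1.49) led the glial and inflammatory lists, and the sterol regulator Srebf2 was lower (-0.34). The 4 measured sex-linked genes had a median of 0.18. Over all nuclei kept, Xist had 3 UMIs in the littermate and 8 in the del-Jak1 library, against 4890 and 7309 UMIs of the Y-linked gene Uty, although the labels call the pools mixed in sex. In satellite glia 12 of 14 glial activation genes were higher with a median of 0.45 (0.40 to 0.63), or 0.15 where nuclei were named by marker scores, led by Apoe, which is also a marker used to name the class, and Serpina3n (1.99).

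The lower level of Il31ra, Htr1f, Pde4c and related genes of NP3 neurons was weighed first. Fewer NP3 nuclei (112 and 86 in the first clustering) as the whole cause would leave the levels inside these nuclei as they were. Yet Il31ra, Htr1f, Pde4c, Osmr and Gpr139 had a median log2 ratio of -2.13 inside the NP3 cluster found without the NP3 markers and named genes. A part in the drop of the class is not excluded. Osmr was -1.11 in Scn10a-high neurons and -0.74 in the first NP3 cluster, and Htr1f -2.11 and -1.79. Il31ra, with -3.77 and -3.96, went the other way. The NP3 cluster of that median was formed without these genes, but its name came from markers that include Il31ra, Htr1f and Osmr. Median UMIs of the nuclei in that cluster had a ratio of 1.002 (0.758 to 1.60) of the del-Jak1 to the littermate library. In the first NP3 cluster the medians were 3402.5 in the littermate and 4298 in the del-Jak1 library. Lower depth was thus not seen, but this is a weak test of it as a cause. Levels in CPM are already scaled by the UMIs of the class. The 12 lowest genes lay on 9 chromosomes, which shows only that they are not all linked to Il31ra. This cannot decide on a variant linked to Il31ra, which could act on Il31ra alone. Several of the 12 genes also differed outside NP3 neurons. Weaker interferon and STAT signalling in neurons that carry the Cre stays open. The interferon response list lay at percentile 0 of random lists, but endothelial nuclei and satellite glia also lay low, at percentiles 0.02 and 0.15. The satellite glia median of -0.16 turned to 0.06 where nuclei were named by marker scores. The median over the 12 members left in thinned Scn10a-high neurons was -0.04 (-0.40 to 0.27), against -0.28 for the same members unthinned. The list of STAT3 targets had a median of 0.12 at percentile 34.2, which turned to -0.10 with members of at least 100 UMIs. That explanation and a difference between the pools cannot be told apart with 1 library per genotype.

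The higher level of ribosomal protein and other cytoplasmic transcripts was weighed last. The ribosomal protein median was above 0 in 8 of 8 classes, from 0.32 in Scn10a-low neurons to 0.79 in satellite glia. Deeper nuclei in the del-Jak1 library as the whole cause are argued against by nuclei matched on UMIs, in which the lower bound of the median stayed above 50% of the main value in 8 of 8 classes. The matched median was 0.63 (0.59 to 0.69) in Scn10a-high neurons and 0.62 (0.56 to 0.69) in satellite glia. More cytoplasmic or free RNA in the del-Jak1 suspension stays open, because the values went both ways. Mitochondrially encoded genes, which it should raise as well, had a median whose interval lay above 0 in 2 of 8 classes, satellite glia (0.37) and Schwann cells (0.45). The interval lay below 0 in Scn10a-high neurons (-0.30), Scn10a-low neurons (-0.21) and fibroblasts (-0.11). The estimated free-RNA share was higher in the del-Jak1 library in every class except Scn10a-low neurons (6.47% and 6.24%). With free RNA subtracted, the ribosomal protein median fell to 0.18 in satellite glia but was 0.83 against 0.61 in Schwann cells and 0.43 against 0.46 in Scn10a-high neurons. No biological explanation was tested for this pattern.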
